A study of Mus musculus with 6 samples.

How the data were processed

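The series holds 6 Illumina BeadChip arrays of mouse embryonic conjunctival epithelium, 1 array for each of 3 embryos with floxed Fgfr2 and Le-Cre (KO) and 3 wild type (WT) embryos. Per the labels' protocols, embryos were taken at embryonic day 14.5, frozen, and sectioned at 10 µm. The fornical conjunctival epithelium was then cut out by laser microdissection after an eosin stain. Each embryo's RNA (15 ng) went through a NuGEN amplification kit for very small inputs, and the cDNA was labelled with biotin, per the labels' protocols. The labels name the dissected tissue as conjunctival epithelium, while their extraction text speaks of future lens tissue; the tissue labels were followed here. All 6 arrays lay on 1 slide, so slide and genotype are not confounded.

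The deposited scanner table gives an average bead signal per probe as an intensity on a linear scale, not background-subtracted and not normalized between arrays, per the file headers and the values. It also gives the standard error of that intensity, the number of beads and a detection p-value against negative controls, per the file headers. The processing was done in GenomeStudio, per the submitters' processing notes, and the version and the normalization method are not given in the sources used here. The series' second deposited table holds the authors' processed intensity values. They rank probes as the scanner values do on each array (Spearman correlation of 1), are on a linear scale, have a median of 9.03 to 9.05 per array and lie below 0 for about 25.6% of probes, and whether they were centred is unknown. They were used only as an alternative.

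Scanner intensities were corrected for background and quantile normalized with neqc in limma 3.58.1 under R 4.3.3, with the background inferred from the detection p-values, an offset of 16 and a log2 transform. Probes with a detection p below 0.05 on at least 3 of the 6 arrays were kept, whatever their group. The array holds 45281 probes, of which 34885 had 1 gene symbol, 18 had several and 10378 had none; symbols were updated through gene identifiers where the reference table held them. The filter kept 20853 probes. For each gene the probe with the highest mean over all arrays was used, which left 13916 tested items, 10418 of them genes with a symbol. No genome build was named in the files, so no coordinates are given.

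KO was compared with WT with limma's lmFit and eBayes, with genotype as the only term and Benjamini-Hochberg adjustment over all 13916 items. Every log2 fold change is KO minus WT, and every adjusted p for a gene comes from this limma fit. A gene undetected on every array of a group with all its probes has only a bound there, and so has a gene named from a probe that was undetected in this way. For such genes the text gives "at least N-fold", the bright group's mean against the dim group's mean of, per array, the higher of the lowest detected signal and the gene's own signal. Gene lists were fixed before the data were examined: 36 lists, of which 31 had at least 5 tested genes and were tested with limma's camera at a preset correlation of 0.01, with adjustment over the lists. Another 4 lists had too few tested genes, and the sex-linked list was read per array. Camera with an estimated correlation and limma's fry were alternatives. List medians were also set against 10000 random lists of the same size, matched on WT level in 20 bins.

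The named genes were chosen by a rule fixed before the data were examined. It took Fgfr2, a set of FGF output and lacrimal bud genes whatever their values, and the 12 largest called changes in each direction among genes with plain symbols whose groups did not overlap. It also took up to 4 members with the smallest p of each list that passed or that marks another cell type. Other choices, also fixed beforehand, were the background correction, offset, scaling, filter, probe choice, variance model, array weights, a replicate block and leaving out each embryo in turn. A filter on KO detection and a run with no scaling between arrays were added after seeing the data.

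The fit was tested on simulated data for the 13916 items of this comparison, with 200 changed genes in each of 10 rounds. With a spread equal in both groups, 57.5% of genes changed by 4 on the log2 scale were found, 3.04% of those changed by 2 and none of those changed by 1, and 8.10% of calls were unchanged genes. With the spread measured in each genotype, the shares found were 56.6%, 21.6% and 0.600%, and 18.2% of calls were unchanged genes, more than the 5% that an adjusted p of 0.05 aims at. In 20 rounds a list with every gene shifted by -1.5 was found 20 times, and 1 of 600 unchanged lists was called. The simulated genes varied independently, so these rates do not cover lists whose genes vary together. The number of arrays limits the precision. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.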

Results

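Gene expression was measured in the fornical conjunctival epithelium of mouse embryos, the fold of surface epithelium between eyelid and eye from which the lacrimal gland buds. The KO embryos carried a floxed Fgfr2 gene and Le-Cre, a Cre driver active in the ocular surface ectoderm, and the WT embryos were wild type on the same mixed background. Each group had 3 embryos with 1 array each. The comparison asks which genes depend on Fgfr2, a receptor for fibroblast growth factors. Only the KO embryos carried Le-Cre, so an effect of Le-Cre itself cannot be told apart from the loss of Fgfr2. On the KO arrays 34.6% ± 0.32 of probes were detected (SD, n = 3), against 49.5% ± 1.04 on the WT arrays (SD, n = 3). The difference of 15.0 percentage points had an exact two-sided permutation p = 0.1, the smallest that 3 against 3 allows. The median gene varied with an SD of 0.80 on the log2 scale between KO embryos and 0.30 between WT embryos. Correlations across genes were 0.70 to 0.71 within KO, 0.94 to 0.96 within WT and 0.75 to 0.77 between groups. Median raw signal was 101 to 106 on the KO arrays and 117 to 126 on the WT arrays. Within a group, 45.9% to 83.1% of detected probes differed between any pair of arrays by more than bead error allows, so no pair looked like 1 library deposited again.

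The targeted gene, Fgfr2, was read by 4 probes. Its brightest probe stood at 12.25 ± 0.12 in KO and 12.09 ± 0.11 in WT (log2 intensity, SD, n = 3), a log2 fold change of 0.16 with SE 0.26 and an adjusted p = 0.79 in limma. Of the other probes, none past the threshold with every probe tested, 2 had log2 fold changes of 0.86 and 0.68. The last was dim, detected on 3 WT arrays and 0 KO arrays, with a bound of 1.13-fold. The labels do not say which exons the floxed allele loses, and a probe outside the deleted part checks nothing, so these values do not check the genotype labels. The sign of the main probe's change turned, to -0.0065 with cyclic loess and -0.32 with no scaling between arrays (adjusted p = 0.43 to 1.00 over all alternatives).

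Of the FGF/ERK output genes, the inhibitors Spry2, Dusp6 and Spred2 were lower in KO embryos. Spry2, a Sprouty inhibitor of receptor signalling, fell from 10.17 ± 0.21 in WT to 6.99 ± 0.45 in KO (SD, n = 3), a log2 fold change of -3.19 with SE 0.34 and a limma adjusted p = 0.015. Dusp6, a phosphatase that acts on ERK, had a log2 fold change of -2.72 (SE 0.46, adjusted p = 0.046). Spred2, another inhibitor of the ERK cascade, had a log2 fold change of -5.16 (SE 0.55, adjusted p = 0.015) and was detected on 1 of 3 KO arrays. On KO arrays B and C it read 4.31 and 4.36, under their lowest detected signals of 5.36 and 5.39. The size of its fall is therefore uncertain. Of the 19 tested genes of the FGF/ERK output list, 3 fell, 0 rose and 16 did not pass. Adjusted over the list alone, 8 were lower and 1 higher. The list's median log2 fold change was -2.29, and camera gave an adjusted p = 0.00019. That call was lost with an estimated correlation (adjusted p = 0.11). The estimate was -0.0016, below the preset 0.01, so a higher correlation among the list's genes does not account for the loss. Flrt3 had a log2 fold change of -1.79 (adjusted p = 0.064), Etv5 of -4.39 (adjusted p = 0.12) and Il17rd of -2.86 (adjusted p = 0.29). Fos, an immediate early gene chosen after its value was seen, had the opposite sign at 2.75 (adjusted p = 0.078). Spry4 and Etv4 were on the array but below the filter, and Spry1 was not analysed here. Dusp6 no longer passed with cyclic loess (adjusted p = 0.058), without a filter (0.053), or without KO replicate A (0.064) or B (0.062), with adjusted p = 0.011 to 0.23 over all alternatives. Spry2, Dusp6 and Spred2 did not pass without any 1 of WT replicates A, B and C. The log2 fold change of Dusp6 was then -2.65, -2.75 and -2.75, so its call was lost while its size changed little.

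Of the lacrimal bud genes, the transcription factors Sox10, Six2 and Barx2 were lower. Sox10 was at least 10.3-fold lower in KO (adjusted p = 0.0041), undetected on all 3 KO arrays and at 8.75 ± 0.28 in WT (SD, n = 3). Six2 was at least 24.5-fold lower (adjusted p = 0.0020), and Barx2 fell from 12.68 ± 0.06 to 10.61 ± 0.17 (SD, n = 3), a log2 fold change of -2.08 (adjusted p = 0.024). Of the 16 tested genes of the lacrimal bud list, 3 fell, 0 rose and 13 did not pass, and 7 were lower when adjusted over the list alone. The list's median was -1.33, or -1.27 with its 3 members undetected in a group at their bounds. Camera gave an adjusted p = 0.00019, against an adjusted p = 0.11 with an estimated correlation. Members that did not pass included Foxc1 at -3.40 (adjusted p = 0.13), Pax6 at -1.11 (adjusted p = 0.34), Sox9 at -0.92 (adjusted p = 0.42), Bmp7 at -0.99 (adjusted p = 0.60) and Eya1, undetected in KO, with a bound of 1.14-fold (adjusted p = 0.072). KO values of Etv5, Foxc1 and Il17rd spread with SDs of 2.42, 1.99 and 2.66, against 0.10, 0.24 and 0.20 in WT. With only genes detected at p below 0.01 on all 6 arrays, the lacrimal list did not pass (adjusted p = 0.22; 1.2e-06 to 0.22 over all alternatives). Six2 passed without each WT replicate, Sox10 without B or C but not without A, and Barx2 did not pass without any 1 of them.

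**Figure D1:**
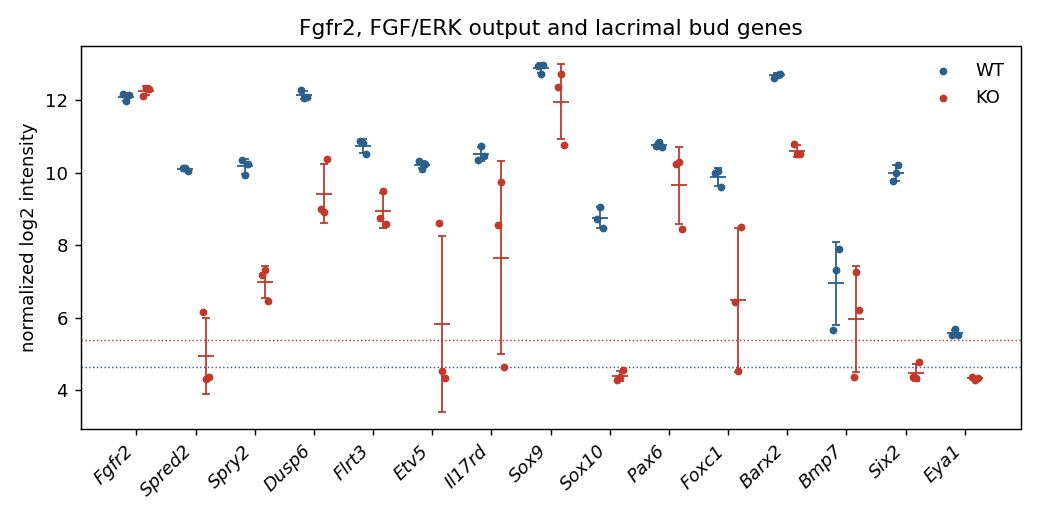
Normalized log2 intensity (vertical axis) of Fgfr2, FGF/ERK output and lacrimal bud genes (horizontal axis), with 1 point per embryo, a bar for the mean and whiskers for the SD of 3 embryos; dotted lines mark each group's mean lowest detected signal. Sox10 and Six2 lie under the KO line on all 3 KO arrays, while Fgfr2 overlaps between groups.

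Most of the largest decreases were in genes bright in WT and undetected in KO, with Spred2, given above, and Fbxo10 as exceptions among the 12 named. Ccdc3 was at least 35.2-fold lower, Cdhr1, a photoreceptor cadherin, at least 30.8-fold, Tmprss11a, a serine protease of squamous epithelia, at least 29.2-fold, and Adh1, an alcohol dehydrogenase, at least 24.6-fold. Aard and Mia followed with bounds of 19.9-fold and 19.7-fold, then Homer2, Cadps2 and Prr15 with 16.5-fold, 16.1-fold and 14.8-fold. Their limma adjusted p-values ran from 0.0020 for Cdhr1 to 0.0041 for Mia. Fbxo10, detected on 1 KO array, had a log2 fold change of -4.83 (SE 0.83, adjusted p = 0.047). On KO arrays A and B it read 4.26 and 4.27, under their lowest detected signals of 5.41 and 5.36, so the size of its fall is uncertain. Ribosomal protein genes also stood lower as a list, with a median log2 fold change of -0.63 over 21 genes, of which 1 fell (Rps13, -1.55, adjusted p = 0.046). Camera gave that list an adjusted p = 0.00077, against an adjusted p = 0.11 with an estimated correlation. Rpl4, Rplp0 and Rps9 had log2 fold changes of -2.58, -1.91 and -0.84 and did not pass. Beside these decreases stood the lower detection on the KO arrays, and 127 of the 221 genes that fell were undetected on every KO array. Of the named genes, Mia did not pass without WT replicate A, Fbxo10 and Rps13 did not pass without any 1 WT replicate, nor without KO replicate B, and Fbxo10 not without KO replicate A nor Rps13 without KO replicate C.

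Connective tissue genes were higher in the KO samples. Col1a1, a fibrillar collagen chain, rose from 5.35 ± 0.69 to 9.99 ± 1.05 (SD, n = 3), a log2 fold change of 4.63 (SE 0.64, limma adjusted p = 0.030). Col1a2 rose by 2.84 (adjusted p = 0.015), Col3a1 by 2.60 (adjusted p = 0.022), and the mesenchymal transcription factor Twist2 by 4.33 (adjusted p = 0.046). Prrx1, another such factor, was at least 5.51-fold higher (adjusted p = 0.030) by a probe undetected on all WT arrays. Of the 22 tested genes of the periocular mesenchyme list, 6 rose, 1 fell and 15 did not pass; 13 were higher and 2 lower when adjusted over the list alone. The member that fell was Foxc2, at -3.25 (adjusted p = 0.035), and the remaining member that rose was Ogn, at least 5.57-fold higher by a probe undetected on all WT arrays (adjusted p = 0.033), both named after their values were seen. The median was 2.26, with a camera adjusted p = 3.0e-08 and an adjusted p = 0.084 with an estimated correlation. With only genes detected at p below 0.01 on all 6 arrays, the list's median was 0.70 and it did not pass (adjusted p = 0.22; 1.9e-15 to 0.22 over all alternatives). Col1a1, Col1a2, Col3a1, Twist2, Prrx1, Foxc2 and Ogn did not pass without any 1 of WT replicates A, B and C, nor Twist2 without KO replicate A or C, nor Prrx1 and Foxc2 without KO replicate C. Osr2, at -1.83, and Sparc, at -0.33, also had negative values and did not pass, named after their values were seen.

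A few WNT pathway genes rose in the same samples. Wnt9b rose by 4.57 on the log2 scale (adjusted p = 0.025), Wnt7b by 2.52 (adjusted p = 0.018), the WNT-responsive factor Lef1 by 3.25 (adjusted p = 0.020) and Apcdd1, a WNT inhibitor, by 4.40 (adjusted p = 0.027). Of the 23 tested list members, 4 rose, 0 fell and 19 did not pass, and 7 were higher and 1 lower when adjusted over the list alone. The list's mean was 0.80 and its median 0.22, which turned to -0.27 with no scaling between arrays. The median of 0.22 lay inside the range of random lists matched on WT level, at percentile 88.82. Camera gave an adjusted p = 0.0032, lost with an estimated correlation (adjusted p = 0.12), without KO replicate A (adjusted p = 0.059) and with genes detected on all 6 arrays (adjusted p = 0.22; 1.2e-05 to 0.22 over all alternatives). Wnt2, outside the list, rose by 4.86 (adjusted p = 0.0093). The 4 list genes did not pass without any 1 WT replicate, and Wnt2 passed without WT replicate C alone. The mesenchyme list, with its median of 2.26, was higher in the same samples.

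Further large increases were seen for Matn4, a cartilage matrix protein, at least 71.2-fold higher (adjusted p = 0.0020), and Dlx2, a homeobox factor, at least 19.7-fold higher (adjusted p = 0.0036). Col8a1 rose by 5.84, Ccn3 by 5.00, the water channel Aqp1 by 4.81, the fatty acid receptor Cd36 by 4.51 and the urothelial plaque gene Upk1b by 4.20 on the log2 scale, with limma adjusted p-values from 0.0047 for Col8a1 to 0.033 for Aqp1. Aqp1 was detected on 1 of 3 WT arrays, and Col8a1, Ccn3 and Cd36 on 2 of 3. Col1a1, Twist2, Wnt9b and Apcdd1, given above, were also detected on 2 of 3 WT arrays. The sizes of these rises rest in part on WT values at background. Globin genes were higher: Hba-a1 rose by 3.02, Hbb-y by 3.16 and Hbb-b2 by 2.06. Globin paralogs share sequence, so which copy a probe read is uncertain. The erythroid list had 6 tested genes, of which 3 rose and 3 did not pass, including Hba-x at 0.88. Its median was 1.47, with a camera adjusted p = 0.00036 and an adjusted p = 0.12 with an estimated correlation. Matn4 passed without each WT replicate, Col8a1 and Dlx2 not without WT replicate A, and Ccn3, Aqp1, Cd36, Upk1b and the 3 globin genes not without any 1 of them; Aqp1 also not without KO replicate B.

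**Figure D2:**
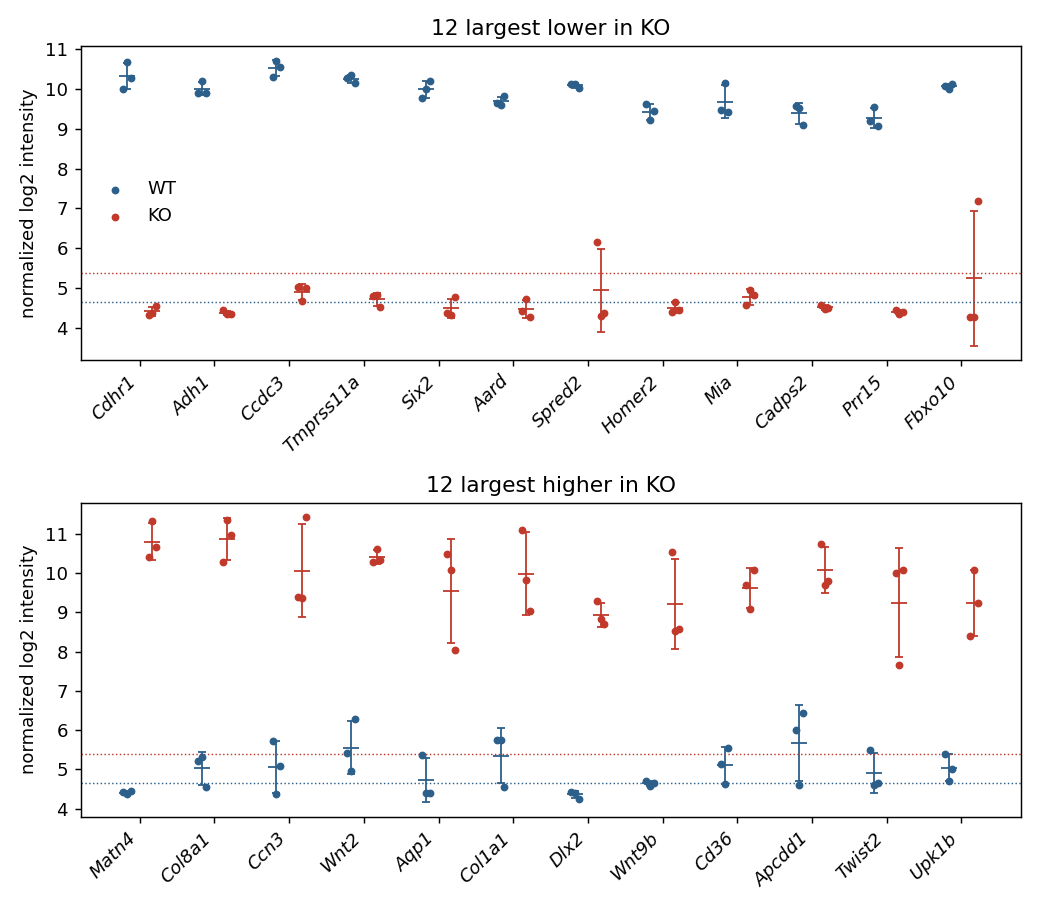
Normalized log2 intensity (vertical axes) of the 12 largest decreases (upper panel) and the 12 largest increases (lower panel) that the naming rule took, with 1 point per embryo, bars for means, whiskers for the SD of 3 embryos and dotted lines for each group's mean lowest detected signal. The naming rule took only genes whose WT and KO points do not overlap, for example Matn4 at 10.80 in KO and 4.41 in WT.

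Of the other cell types, the lens, melanocyte and neural crest, and leukocyte lists were tested and did not pass. The retina and pigment epithelium, muscle, endothelium and nerve lists had too few tested genes for camera. Of 7 tested lens genes, Cryab rose by 1.97 (adjusted p = 0.029, not past without any 1 WT replicate), while Cryba1, Maf and Crygb had values of -1.40, -0.84 and 0.58 (list adjusted p = 0.49). Crygb's sign turned, to -0.0033 with median scaling and -0.32 with no scaling. The melanocyte and neural crest list, which shares Sox10 with the lacrimal list, had a median of -0.53 over 7 genes, or -0.34 with undetected probes at their bounds (adjusted p = 0.069). Ednrb and Kit, read by probes undetected on all KO arrays, had bounds of 1.19-fold and 1.27-fold, and Mitf had a log2 fold change of -0.45. The leukocyte list had a median of -0.96 over 7 genes, or -0.32 with 3 undetected genes at their bounds (adjusted p = 0.33). Tyrobp, Mrc1 and Cx3cr1, undetected in KO, had bounds of 1.32-fold, 1.25-fold and 1.06-fold, and Laptm5 had a log2 fold change of -1.77. General epithelium genes had a median of -0.32 over 21 genes (adjusted p = 0.42). In all, 25 of 31 lists did not pass, with a smallest adjusted p = 0.069, and for Hedgehog signalling, the EGF family and cell cycle inhibitors the median, mean and test differed in sign.

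**Figure D3:**
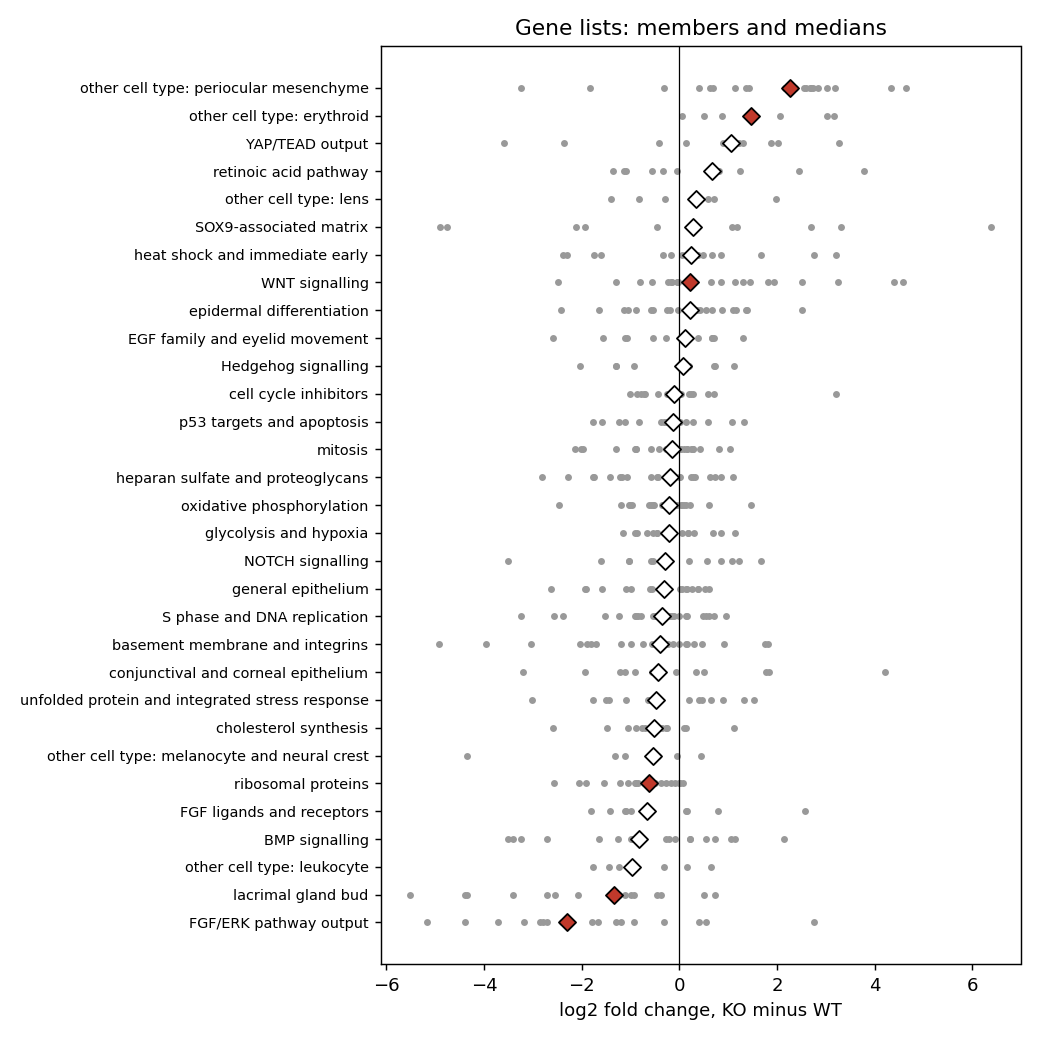
Log2 fold change, KO minus WT (horizontal axis), of the tested members of each of 31 gene lists (vertical axis), with grey points for genes and diamonds for list medians, red where camera passed at an adjusted p of 0.05. The 6 red lists run from FGF/ERK output at -2.29 to periocular mesenchyme at 2.26, and 0 pass with an estimated correlation (smallest adjusted p = 0.084).

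In all, limma called 336 of 13916 items at an adjusted p of 0.05, with 115 higher and 221 lower in KO (65.8% lower), and all 336 changed at least 2-fold by the fitted values. The share of lower genes moved with the scaling: 963 of 1068 calls were lower with median scaling, 127 of 245 with cyclic loess and 1981 of 2068 with no scaling. Groups did not overlap for 28.5% of all tested items, where chance gives 10%. At an unadjusted p of 0.05 the count was 2702. Leaving out WT replicate A, B or C left 12, 22 and 32 calls and 10, 14 and 15 of the 38 named genes called here, and leaving out a KO replicate gave 554 to 569. Simulated arrays with the spread of each genotype gave 18.2% unchanged genes among the calls.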

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

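No scaling and the filter on KO detection were chosen after seeing the data. The count of 336 changed genes (115 higher, 221 lower) moved with several choices, and the cause was not tested unless given. Scaling set the balance: median scaling gave 1068 calls with 963 lower (90.2% lower) and moved the median of all genes by -0.40, while cyclic loess gave 127 lower of 245 (51.8%) and moved it by 0.18. No scaling gave 2068 calls with 1981 lower (95.8%) and moved it by -0.72. Without a filter there were 660 calls, 311 higher and 349 lower, and 12 lists; with detection p below 0.01 on all 6 arrays there were 189 calls, 94 lower, and 1 list, with fewer genes tested. Only genes detected on at least 2 KO arrays gave 140 calls with 45 lower, by a filter that removes genes undetected in KO. Array weights gave 185 calls, 61 higher and 124 lower. Adjusted p below 0.10 gave 764 calls and unadjusted p below 0.05 gave 2702. Leave-one-out counts ran from 12 to 569, with 1 to 198 higher and 11 to 393 lower: 12, 22 and 32 without WT replicates A, B and C, and 562, 569 and 554 without KO replicates A, B and C. KO values spread more than WT values (median SD 0.80 and 0.30). Camera with an estimated correlation passed 0 lists (smallest adjusted p = 0.084, with 6 at an unadjusted p below 0.05). Fry passed 17 in a single direction and 26 in either direction. The estimated correlation was -0.0016 for FGF/ERK output, -0.015 for WNT, -0.025 for ribosomal proteins and 0.0016 for mesenchyme. These lie below the preset 0.01, so a higher correlation does not account for those lost calls. It was 0.012 for the lacrimal list and 0.078 for the erythroid list.

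Fgfr2's main probe, not past the threshold in any setting, reversed to -0.0065 with cyclic loess and -0.32 without scaling. Crygb went to -0.0033 with median scaling and -0.32 without scaling. Lists reversed in camera's direction were SOX9-associated matrix (medians 0.15 without background correction, 0.22 with offset 50, 0.64 with loess), conjunctival and corneal epithelium (-0.57 with median scaling, -0.89 without scaling), glycolysis and hypoxia (-0.50 with median scaling) and NOTCH signalling (-0.026 with loess, 0.29 without a filter, -0.87 without scaling). So did the EGF family (-0.034 without a filter), heparan sulfate (0.018) and p53 targets (-0.027), the last pair with detection on all 6 arrays. With an embryo left out in turn, values ran from -0.33 to 0.69 for SOX9-associated matrix, -0.51 to -0.099 for NOTCH, -0.47 to -0.25 for conjunctival and corneal epithelium, -0.29 to -0.035 for glycolysis, -0.49 to 0.33 for Hedgehog signalling, -0.16 to 0.24 for the EGF family and -0.063 to 1.14 for Crygb. The WNT median turned to -0.27 without scaling, while camera's direction stayed up and the list passed (adjusted p = 1.2e-05). Over the named genes, 891 values under alternatives kept direction and side of the threshold, 150 no longer passed, 30 newly passed and 3 reversed. Signal over background limits genes undetected in a group, which have only a bound.

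The replicate letters A, B and C are shared by the groups, and the labels do not say that they pair embryos. Same-letter deviations correlated at -0.029, -0.0043 and -0.0052, so no pairing was seen. With 3 embryos per group and the wide KO spread, a pairing could be missed and is not excluded. With the letter as a replicate block, limma called 0 genes (0 higher, 0 lower), with 2079 at an unadjusted p below 0.05, and camera passed 6 lists.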

Other observations

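Some genes of lists that did not shift as a whole changed; these were named after their values were seen, except Matn4, Mia and Upk1b, which the rule had taken. Among genes of the SOX9-associated matrix list, Col9a1 was at least 13.2-fold lower, Col9a3 at least 2.14-fold lower and Mia at least 19.7-fold lower in KO, while Matn4 was at least 71.2-fold higher (list median 0.28, camera adjusted p = 0.94). The retinoic acid gene Crabp1, a binding protein, rose by 3.79 on the log2 scale (limma adjusted p = 0.018). Cyp26a1, a degrading enzyme of the same list, was at least 4.76-fold higher (limma adjusted p = 0.031). Their list had a camera adjusted p = 0.29. The epithelial transcription factor gene Elf3 fell by 1.94 on the log2 scale and the tight junction gene Cldn10 was at least 4.40-fold lower by a probe undetected on all KO arrays, while Upk1b rose by 4.20 (list median -0.44, adjusted p = 0.67). Itga3, an integrin chain of basement membrane adhesion, had a log2 fold change of -3.96 (adjusted p = 0.0075). Hey1, a NOTCH and BMP target, had a log2 fold change of -3.51 (adjusted p = 0.046), and the homeobox gene Dlx3 rose by 2.13 (adjusted p = 0.032). Btg2, an antiproliferative gene, rose by 3.21 (adjusted p = 0.0094), while S phase genes (median -0.36, adjusted p = 0.25) and mitosis genes (median -0.14, adjusted p = 0.43) did not pass. Of these 13 genes, 2 passed without WT replicate A (Col9a1 and Matn4), 3 without B (also Mia) and 4 without C (also Mia and Itga3), and 13, 12 and 11 without KO replicates A, B and C, Elf3 being lost without B or C and Hey1 without C.

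Xist, the noncoding RNA of the inactive X chromosome, was read by 4 probes at 9.32 to 9.95 on all 3 WT arrays. On the KO arrays the probes were detected on 1, 2, 0 and 1 of 3 arrays. Of the Y-linked genes, 1 probe of Eif2s3y, at 7.82 to 8.79, and 1 of Kdm5d were detected on all 6 arrays. The labels do not give the embryos' sex. A sex difference between the groups is therefore not excluded, and it could not be told apart from genotype.

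Tests chosen after the values they measure were seen were those on dim genes, on FGF output genes and on captured mesenchyme; the condition on spread in the test of other cell types, and its extensions to all such lists and to genes near background, were also added after its medians were seen. The 336 calls stand beside a highest count of 0 in the other splits of the 6 arrays, and the 6 lists beside 1; in 1 of 10 splits, the real one, the count was as large, and 10 splits are too few for a share under 0.05.

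Many genes that fell were undetected on all KO arrays, on arrays that also detected fewer probes. Independent loss from each library at a single rate for all genes of the same WT level is argued against. Of 12286 genes detected on all WT arrays, 1021 were undetected on all KO arrays, 1.71 times the 598 predicted (95% Poisson interval 550 to 646). The prediction came from each array's loss at the same WT level. Independent loss at rates that differ between genes of the same WT level would also exceed it, so that stays open. The 1021 are all such genes, not only the 127 that fell. For loss of single fragments, 27 of 40 further probes of the 127 pattern genes were undetected in KO too (67.5%, exact interval 50.9% to 81.4%). That was 4.34 times the 15.5% for any gene. The brightest probe over all arrays was kept, so a further probe still bright in KO would tend to have been kept instead. This selection can raise the share, so loss of single fragments stays open. Deviations of 2 probes of a gene correlated at 0.20 among KO embryos and 0.16 among WT embryos (3799 genes). A lower yield that takes dim genes first stays open, with the pattern genes at a median WT percentile of 50.2 (bootstrap 47.8 to 53.1). Poorer RNA shared by all KO libraries could not be separated from the loss of Fgfr2, as every such library is a KO library.

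FGF/ERK output genes were lower as a list. A loss set by WT level alone, gene by gene, is argued against, because the list's median lies below -0.59, the 2.5th percentile of 10000 matched random lists. Random lists hold unrelated genes, so a loss shared by genes that vary together is not excluded. Some lists that camera did not call also lay outside their random range. BMP signalling was at percentile 0.19 and YAP/TEAD output at 99.97, while others lay inside, such as glycolysis and hypoxia at 49.69. WNT signalling, which camera called, also lay inside its range, at percentile 88.82. Loss of signalling through the deleted receptor is a candidate explanation, with the list's median of -2.29, but that value restates the pattern. The list's camera call was lost with a correlation estimated at -0.0016 (adjusted p = 0.11). Several of these genes were missing from some KO arrays, so the loss described above stays open for part of the list.

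Mesenchymal genes were higher in KO as a list, a call lost with an estimated correlation (adjusted p = 0.084) and with detection on all 6 arrays (adjusted p = 0.22; 1.9e-15 to 0.22 over all alternatives). If a lower share of epithelium were the whole account, it would raise every other cell type alike. Of the endothelium, leukocyte, muscle and nerve lists, 3 had medians at or below 0. With undetected probes at their bounds, these medians were -0.52, -0.32, 0.35 and -0.079. In median, 21 mesenchyme genes differed by 2.32 from 33 genes of all other cell types, erythroid included (two-sided permutation p = 1e-05). That p is the smallest that 100000 permutations give, across genes, which are not independent replicates. With only genes at least 1 log2 unit above background in a group, the difference was 2.73 over 20 and 17 genes (p = 0.0014), and 3.28 over 21 and 8 for the 4 lists without bounds (exact permutation p = 0.0030). The comparisons with all other cell types left out Foxc2, the member that fell, which another list also holds. A gene that passed the detection filter through 1 group alone has its direction set by that. By the probes used, Tyrobp, Mrc1, Cx3cr1, Kit and Egfl7 were detected in WT alone, and Prrx1 and Ogn in KO alone. Detection was lower on the KO arrays, so these comparisons do not settle whether a lower share is the whole account. The erythroid list goes with a lower share of epithelium, with 6 of 6 values positive and a median of 1.47. The endothelium and nerve medians rest on 2 genes each, of opposite sign, and the muscle median on 3. A lower share, as the whole account or part of it, stays open. Fewer epithelial cells cannot be told from none, with the general epithelium median at -0.32, and more mesenchyme in the KO sections, despite the microdissection, may also be part of it, but its value, 86.4% of members above 0, restates the pattern, Foxc2 fell by 3.25, Osr2 was at -1.83, 11 of 22 members were detected on all WT arrays and 1 is in another list; a change within KO epithelial cells was not tested and stays open.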
